A study of Mus musculus with 10 samples.

How the data were processed

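The samples were small-RNA libraries of RNA pulled down from pancreatic β-cells. Per the labels' protocols, CD4-positive, CD25-negative T cells of BDC2.5 mice, whose T-cell receptor transgenes direct them against the islets, were activated and labelled for 48 h with 200 µM ethynyl uridine (EU, a uridine analogue that can be coupled to biotin by click chemistry). These cells were injected into the tail vein of NOD.SCID mice, a strain without mature lymphocytes of its own, and control mice received saline. After 48 h the islets were dissociated and CD45-negative β-cells were sorted by autofluorescence from female mice aged 8 to 12 weeks. EU-tagged RNA was biotinylated, captured on streptavidin beads from equal amounts of input RNA and sequenced with a QIAseq miRNA library kit. The 10 libraries form 2 groups of 5, called EU (mice given T cells) and CT (mice given saline). CT mice received neither EU nor T cells, so CT libraries measure what the beads carry over without a tag in mice without injected T cells. Effects of the tag and of the T cells cannot be told apart in this design. Libraries of both groups carry the letters A, C, D, G and H. The labels do not state whether a library is 1 mouse or a pool, so p-values measure the spread between these libraries, which may be technical.

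The deposited table holds raw counts per fragment sequence, per the file headers, and the authors' mapping tool, tRNA reference and genome build are not given in the sources used here. It also holds a signal column per library in which the authors divided the counts by 1 factor per library, as the deposited values show, log2-scale values from the authors that were not used in any test, and 2 further kinds of value from the authors' own comparison. These are signed linear fold changes, which the deposited table writes as a score with a minus sign for a decrease, and the p-values of that comparison with their adjusted form, which the authors deposited without the name of the test. R 4.2.2 and DESeq2 1.38.3 were used, per the submitters' processing notes, which do not say for which step. A sequence that matches several tRNAs stands on a row for each of them. The 364 rows were therefore collapsed to 251 different sequences, and repeats of a sequence never differed in their counts. Of these, 244 sequences of 16 to 30 nt carry tRNA names, and 83 of them carry the names of several tRNAs, which cannot be told apart by sequence. Another 5 sequences carry the name miR-238, and 2 carry no name. The unnamed sequences held between 0.0248% and 0.467% of a library's counts and were left out of library sizes and tests.

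Totals were sums over this table of tRNA-related sequences, from 4903 to 32314 counts per library, and are not the sequencing depth of the libraries, which is not given in the sources used here. At those totals 1 count is worth between 30.9 and 181 CPM (counts scaled to library size with TMM factors), so sequences with few counts are imprecise. Summed families were given TMM factors of their own, so their CPM differ somewhat from the sums of the CPM of their members. Whether a count is a read or a distinct molecule is not given in the sources used here, so intervals cover counting error only.

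The table has no coordinates, so positions are given within the mature tRNA. A sequence ending in CCA, the trinucleotide added to the 3' end of every mature tRNA, was called 3'-CCA (50 sequences). A sequence in which the conserved bases of the D arm follow directly on the first 7 nt, the length of the acceptor stem, was called 5'-end (126), and the remaining 68 were called internal, although some could start or end near a terminus. The 5'-end pattern also took in GCTCAGTTGGTAGAGC of Lys-CTT, Lys-TTT and Tyr-GTA (158 counts), which starts within the D arm and was left in that class. No name in the table marks a mitochondrial tRNA, so the planned share of mitochondrial tRNA was not computed. All 244 tRNA sequences were searched for exact sense matches in 141767 GENCODE M21 transcripts, and 50 had at least 1, so counts of these can include other transcripts. None of the 6 Lys-CTT 5'-end sequences had a match.

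Groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, no covariate) in R 4.3.3, with Benjamini-Hochberg adjusted p below 0.05 as the threshold. Standard errors of log2 fold changes were derived from the F statistic. DESeq2 1.42.0 and limma-voom 3.58.1 were alternatives. Sets of at least 5 tested sequences (isotypes, classes and the 63 sequences with the highest uridine share, 22.2% or more) were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Camera compares a set with the other sequences, whereas fry tests it against no change. Per-library values were compared with two-sided exact permutation tests over the 252 assignments of 5 against 5 libraries, whose smallest p is 0.00794. Detection was counted after thinning each library to 4903 counts, as the mean of 20 draws. The named sequences were those past the threshold, up to 10 per direction, filled up to 20 with the smallest unadjusted p, and the 5 with the highest mean CPM. None passed, so the first 20 are those with the smallest p. Marker miRNAs of β-cells, leukocytes, erythrocytes, acinar and endothelial cells had been listed in advance, and the table names none of them. These choices and the main alternatives (other factors, filters and tools, the letter as a block, each library left out) were fixed before the data were examined.

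Letters were checked for pairing. Deviations from the group means correlated between same-letter libraries at r = 0.337 (A), 0.213 (C), 0.157 (D), 0.333 (G) and 0.585 (H), all above 0.1, which met the limit set for taking the letters to pair the libraries. Libraries of other letters from the same set of letters (A, C and D, or G and H) correlated at -0.116 to 0.464, with a median of 0.207 against 0.333 for the same letter. CT A correlated best with EU C (0.464) and CT D with EU C (0.316), so this check did not separate the letter from the set of letters. The pairing comes from these data and not from the labels. A sign permutation within letters has 32 patterns and cannot give p below 0.0625. One of the unnamed sequences, with an undetermined base, had 143 counts in the libraries A, C and D and 0 in G and H, which was read as a hint of 2 sequencing batches, and values are also given within each set of letters. Within A, C and D the smallest possible exact p is 0.1, and within G and H it is 0.333.

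The tests were tried on simulated data made from the 249 named sequences with 60 changed in each of 20 simulations. For the EU against CT comparison edgeR recovered 5% of 2-fold, 32.3% of 4-fold and 67.8% of 8-fold changes, with 2.78% of its calls false. DESeq2 recovered 13.3%, 64.3% and 95.5%, with 7.86% false. The set test found the 3'-CCA class, raised 2-fold, in 20 of 20 simulations and made a call in 1 of 20 without any change. Sequences were simulated independently, without sets of letters or correlation between overlapping fragments, so none of these rates need hold for the real libraries. Over 100 splits of the real libraries (below) the median was 3 set calls. Per-library values, permutations and plots used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.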

Results

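The study asked whether tRNA-derived fragments made in CD4-positive T cells reach β-cells in the first days of an autoimmune attack on the islets. RNA of T cells was tagged with EU before transfer. The design takes tagged fragments found in sorted β-cells to have come from the injected cells, an assumption that was not tested here. The pull-down from saline-injected mice served as the background. The 5 CT libraries held between 4903 and 16847 counts and the 5 EU libraries between 7497 and 32314. Mean log2 totals were 13.30 ± 0.77 (SD, n = 5) in CT and 13.96 ± 0.99 in EU, and this 1.58-fold difference was within the spread between libraries (exact permutation p = 0.262). It was of similar size within letters A, C and D (13.32 and 14.01) and within G and H (13.28 and 13.88). The background libraries also held most of the 249 named sequences, each of which had at least 56 counts over all libraries. After thinning to equal totals, 238 ± 7.27 sequences were detected in CT and 232 ± 7.61 in EU (SD, n = 5, exact permutation p = 0.230), with 241 and 235 within A, C and D and 234 and 226 within G and H. Without thinning the means were 245.4 and 244.8 (exact p = 0.905). With so few rare sequences listed, detection lay near its ceiling and says little of how the groups differ in complexity.

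Among single fragments, the 5'-end pieces of tRNA Lys-CTT included the largest fold over background and the smallest unadjusted edgeR p. These fragments cover the acceptor stem and D arm of a lysine tRNA, and those of 28 nt or more also reach the anticodon arm. All 6 tested members were higher in EU, with a median of 5.03-fold, and they were the only family of 5 or more tested sequences in which all members reached an unadjusted p below 0.05. The 2 tested Phe-GAA 5'-end sequences had a similar median, 5.09-fold. The 29-nt GCCCGGCTAGCTCAGTCGGTAGAGCATGA had 504 ± 206 CPM in CT and 6607 ± 7874 in EU (SD, n = 5), a log2 fold change of 3.75 ± 0.88 (SE). The 26-nt GCCCGGCTAGCTCAGTCGGTAGAGCA had 1621 ± 177 and 7523 ± 5639 CPM (2.21 ± 0.54), and the 28-nt GCCCGGCTAGCTCAGTCGGTAGAGCATG had 1408 ± 644 and 6667 ± 5293 CPM (2.24 ± 0.61). In these 3, each of the 5 EU libraries lay above the highest CT library. The margin was narrow in 2 of them, as 1 count in CT H is worth 181 CPM. The 29-nt sequence had 772 CPM in EU C and 723 in CT H (4 counts), and EU D rested on 9 counts. The 28-nt sequence had 2401 CPM in EU G and 2169 in CT H (12 counts). The 30-nt GCCCGGCTAGCTCAGTCGGTAGAGCATGAG (2.87 ± 0.84) and the 25-nt GCCCGGCTAGCTCAGTCGGTAGAGC (2.42 ± 0.85) were above the highest CT library in 3 and 2 EU libraries. Single libraries weighed on these values: without EU A the log2 fold change of GCCCGGCTAGCTCAGTCGGTAGAGCATGA was 2.78, and without EU H those of the 30-nt and 25-nt sequences were 2.14 and 1.52, while the 25-nt one was at 3.24 without CT H. The sixth member, GCCCGGCTAGCTCAGTCGGTAGAGCATGG (2.02 ± 0.94), rested on EU D, and without that library its log2 fold change was 0.16.

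No single fragment passed the planned threshold. Of 184 sequences tested with edgeR, 0 had an adjusted p below 0.05, the smallest adjusted p was 0.0878, and 11 had an unadjusted p below 0.05, where 9.2 would be expected by chance. The unadjusted count was 41 without EU H, and 9 to 12 without any other single library. With limma-voom 0 passed as well, with 12 at an unadjusted p below 0.05. DESeq2 on the same counts called 6, all higher in EU. These were 5 of the Lys-CTT 5'-end sequences, with adjusted p from 4.08e-04 to 0.0381, and 1 Phe-GAA sequence with adjusted p = 0.0369. Within A, C and D DESeq2 also called 6, of which 2 were among these 6 and 2 were lower in EU, and gave 1 other of these 6 no adjusted p. Within G and H it called 0. With a term for the set of letters it called 5 of these 6 and gave GCCCGGCTAGCTCAGTCGGTAGAGCATGA no adjusted p. With the letter as a block DESeq2 called 3, all of them Lys-CTT 5'-end sequences, while edgeR still called 0, with 28 at an unadjusted p below 0.05. The authors' deposited table lists the same 6 sequences below an adjusted p of 0.05, with folds from 4.55 to 13.7. A second set of folds by the authors, headed apeglm, ran from 3.84 to 10.6 for them. Both rest on the same counts and are not independent evidence. Adjusted over the list alone, 4 of 35 lysine, 2 of 2 phenylalanine and 2 of 89 5'-end sequences passed in edgeR, and 0 in each other isotype or class.

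Summed over its 6 members, the Lys-CTT 5'-end family rose from 6825 ± 2584 CPM in CT to 36608 ± 27398 in EU (SD, n = 5), a log2 fold change of 2.42 ± 0.56 (SE) with an edgeR adjusted p of 0.0397 over 51 families, a sum chosen after the values of its members were seen. The log2 fold change was 2.80 within letters A, C and D (adjusted p = 0.105) and 1.88 within G and H (adjusted p = 0.988), and 2.10 with the letter as a block (adjusted p = 0.0173). The increase was uneven. Libraries EU A, EU D and EU H had 61965, 28410 and 69082 CPM, while EU C had 10021 and EU G 13564, against a highest CT value of 11212. The adjusted p was above 0.05 without any one of CT A, CT C, CT D, CT G, EU A, EU D and EU H, at most 0.112, with log2 fold changes from 1.98 to 2.37.

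**Figure D1:**
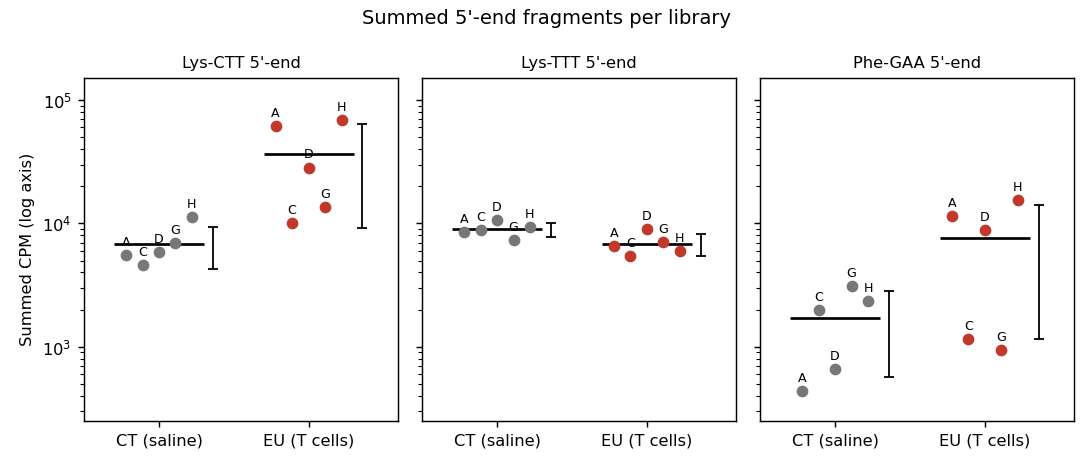
Summed CPM of the Lys-CTT, Lys-TTT and Phe-GAA 5'-end fragments on a log axis, for each CT and EU library (points with letters), with group means (lines) and SD (bars, n = 5). EU A, D and H reach 28410 CPM or more for Lys-CTT, whereas the Lys-TTT values of both groups lie between 5442 and 10640 CPM.

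The closely related tRNA Lys-TTT, which reads the other lysine codon, gave no such difference. Its 5'-end sequence differs from that of Lys-CTT by C7A in the 25- and 26-nt fragments, counted from base 1 of the mature tRNA with the Lys-CTT base first. The summed Lys-TTT 5'-end fragments had 8938 ± 1215 CPM in CT and 6828 ± 1395 in EU (SD, n = 5; log2 fold change -0.39 ± 0.31, edgeR adjusted p = 0.805), with -0.25 within A, C and D and -0.53 within G and H. The value was 0.88, without passing the threshold, when libraries were scaled to their miR-238 counts, which moved the median of all single sequences from 0.05 to 1.26. The ratio of Lys-CTT to Lys-TTT 5'-end counts, which no scaling can change and which was chosen after the values were seen, had a mean log2 of -0.45 ± 0.52 in CT and 2.05 ± 1.26 in EU (SD, n = 5). All 5 EU libraries were above the highest CT library (exact permutation p = 0.00794, the smallest the design can give). The means were -0.81 and 1.92 within A, C and D and 0.08 and 2.24 within G and H, and the sign permutation within letters gave p = 0.0625, the smallest it can give. Both parts of the ratio contributed: as a share of tRNA counts Lys-CTT 5'-ends had means of 1.20% and 4.93% (exact p = 0.0635) and Lys-TTT 5'-ends 1.59% and 0.906% (exact p = 0.0317, and 0.0625 by sign permutation within letters). Within A, C and D the Lys-CTT shares were 0.959% and 5.15% and the Lys-TTT shares 1.70% and 1.06%, and within G and H they were 1.55% and 4.59%, and 1.43% and 0.672%.

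Fragments from the 5' end of tRNA Phe-GAA, the phenylalanine tRNA, were higher in EU in part of the libraries. GCCGAAATAGCTCAGTTGGGAGAG had 656 ± 507 CPM in CT and 4050 ± 4602 in EU (SD, n = 5; log2 fold change 2.69 ± 0.90), and GCCGAAATAGCTCAGTTGGGAGAGC had 1086 ± 791 and 4357 ± 4333 CPM (2.00 ± 0.87). Neither passed in edgeR (adjusted p = 0.329 and 0.743), and each was above the highest CT library in 3 of 5 EU libraries. Without EU H the first was at 1.76, and without EU A the second at 1.35. The Cys-GCA fragment GGGGGTATAGCTCAGTGGTAGAGC had a log2 fold change of 2.74 ± 1.01 (adjusted p = 0.412) that came from EU D, with 374 counts there, and was 0.22 without it. DESeq2 gave no p for it with all libraries, and called it without EU A (adjusted p = 0.0404) and without EU G (adjusted p = 0.0136), both fits that keep EU D.

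The other named fragments did not pass either, and their edgeR adjusted p lay between 0.600 and 0.897. Among tryptophan tRNA fragments, CACGTCGGGGTCACCA and ATCACGTCGGGGTCACCA, both from the 3' end of Trp-CCA, were 1.98-fold and 2.61-fold higher without passing, and 7 of 7 tested Trp sequences were above 1-fold. Without EU A, ATCACGTCGGGGTCACCA was at a log2 fold change of 0.44. The 3' fragment CCCTGTTCGGGCGCCA of Lys-TTT, which also matches 1 other transcript, was at 0.92 ± 0.53. On the lower side, the proline fragments TGCGAGAGGTCCCGGG and TGCGAGAGGTCCCGGGT, shared by Pro-AGG, Pro-CGG and Pro-TGG, were at -1.40 ± 0.57 and -0.96 ± 0.54. GTCAGGATGGCCGAGTGGTCT of Leu-CAA and Leu-CAG was at -1.48 ± 0.73 (-2.16 without EU H), GTAGCTCAGCGGTAGAGC of Ala-TGC at -1.26 ± 0.66, ATAGCTCAGTCGGTAGAGC of Lys-TTT at -1.58 ± 0.82 and GCTCAGTCGGTAGAGC of both lysine tRNAs at -1.21 ± 0.65. Both of these lysine values rested on CT H, and without it they were -0.41 and -0.22. The alanine fragment GGGGATGTAGCTCAGT, at -0.86 ± 0.48, matches transcripts of 14 other genes, and the lysine fragment GCTCAGTCGGTAGAGC of 2, so their counts are uncertain. Scaled to miR-238 counts, GGGGATGTAGCTCAGT and TGCGAGAGGTCCCGGGT were at 0.41 and 0.19, below the median of all sequences under that scaling (1.26).

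The most abundant sequences showed no difference beyond the spread. The 16-nt GGGGATGTAGCTCAGA of Ala-CGC, with 9.68% of all counts, had 58784 ± 57566 CPM in CT and 141019 ± 135483 in EU (SD, n = 5; edgeR adjusted p = 0.853), and its direction differed between the sets of letters. The Ala-CGC GGGGATGTAGCTCAGA log2 fold change was -0.45 within A, C and D and 2.81 within G and H, and 2.03 without CT A. The 3 most abundant aspartate sequences all ended in CCA. ACCGGGGTTCGATTCCCCGACGGGGAGCCA, CGGGGTTCGATTCCCCGACGGGGAGCCA and CCGGGGTTCGATTCCCCGACGGGGAGCCA had log2 fold changes of 0.72 ± 0.47, 0.69 ± 0.58 and 0.52 ± 0.54. The 19-nt miR-238 sequence, with 23.6% of all counts, was at -0.92 ± 0.63 and the 20-nt one at -1.02 ± 0.58, neither passing, with -1.51 and -1.65 without EU H.

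By position within the tRNA, fragments from the 3' end tended to lie above and internal fragments below background. Of 40 tested 3'-CCA sequences 39 had folds above 1, with a median of 1.52-fold, and of 50 internal sequences 37 had folds below 1, with a median of 0.764. The 89 tested 5'-end sequences were split into 49 above and 40 below. With a preset correlation, camera gave adjusted p = 1.38e-07 for 3'-CCA sequences (higher) and 2.08e-09 for internal sequences (lower), and it also placed the 5 miR-238 sequences (adjusted p = 0.00432) and the 17 alanine sequences (adjusted p = 0.0174) lower. All 4 calls were lost with an estimated correlation (adjusted p = 0.496 for each). The fry test, which asks whether a set differs from no change and not from the other sequences, gave adjusted p from 0.413 to 0.644 for these sets. The alanine call was also lost without CT A, CT C, CT G, EU A, EU D or EU H (adjusted p from 0.0556 to 0.265) and within either set of letters, and the miR-238 call without EU G (adjusted p = 0.0525). On the log2-CPM scale of this test the internal sequences had a median of 0.16 within G and H, against -1.11 within A, C and D, and the 3'-CCA sequences 0.52 and 0.61. Within G and H neither class passed (adjusted p = 0.873 and 0.403). These directions are relative to the other sequences of a library: the median log2 fold change of all sequences was 0.05, but 1.26 when scaled to miR-238 counts. Of the other 11 sets, which were the remaining isotypes, the 5'-end class and the sequences with most uridine, none passed, the smallest adjusted p being 0.159 for tryptophan, whose set passed within G and H (0.0201) and without EU D (0.0224). The 5'-end class passed without EU A (0.0251), with a median of -0.01 and a mean of 0.12 in all libraries.

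**Figure D2:**
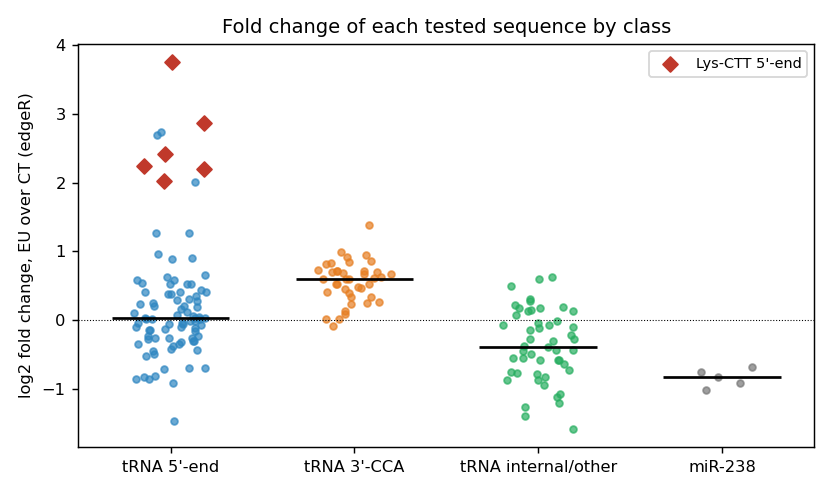
Log2 fold change of EU over CT (edgeR) for each of the 184 tested sequences, by class, with the class median as a line and Lys-CTT 5'-end sequences as diamonds. The 3'-CCA sequences lie above 0 in 39 of 40 cases and the 5 miR-238 sequences all lie below 0.

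As shares of the library total, miR-238 differed most. It took 42.1% ± 9.05 in CT and 21.3% ± 11.9 in EU (SD, n = 5; exact permutation p = 0.0238, adjusted p = 0.0952 over 4 classes), lower than every CT library in 4 of 5 EU libraries and lower than its letter partner in 5 of 5. The means were 35.96% and 17.5% within A, C and D and 51.3% and 27.1% within G and H. The difference did not pass the adjustment, except without EU H (difference of -25.3 percentage points, adjusted p = 0.0317). Shares of 5'-end sequences were 26.1% ± 5.03 and 38.3% ± 14.1 (adjusted p = 0.238), with 29.4% and 35.95% within A, C and D and 21.3% and 41.9% within G and H. Those of 3'-CCA sequences were 20.9% ± 6.66 and 32.6% ± 19.1 (adjusted p = 0.349) and those of internal ones 10.8% ± 5.16 and 7.69% ± 5.07 (adjusted p = 0.349), from the same exact permutation tests with n = 5. Within A, C and D the 3'-CCA shares were 25.5% and 42.1% and the internal ones 9.17% and 4.42%, and within G and H they were 14.01% and 18.4%, and 13.3% and 12.6%. These shares depend on miR-238, whose lower share in EU raises the rest. Of tRNA counts alone, 5'-end sequences took 45.1% in CT and 49.0% in EU (exact permutation p = 0.611), but 45.8% and 43.1% within A, C and D. The 3'-CCA sequences took 35.7% and 40.4% (exact permutation p = 0.659), but 29.0% and 23.7% within G and H.

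**Figure D3:**
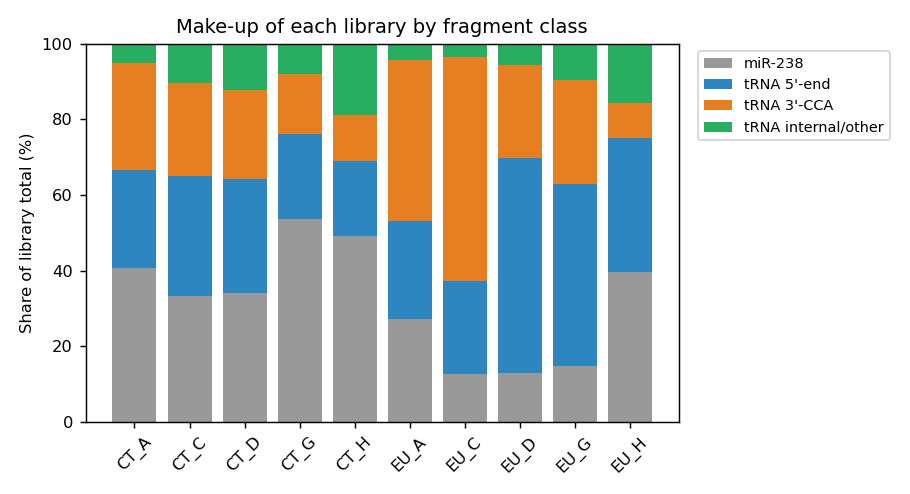
Share of each library's total counts in percent held by miR-238, tRNA 5'-end, tRNA 3'-CCA and other tRNA sequences, for the 5 CT and 5 EU libraries. The miR-238 share averages 42.1% in CT and 21.3% in EU, with EU H at 39.6% (95% Wilson interval 38.5 to 40.6%).

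Among the isotypes, aspartate, alanine, lysine and leucine tRNAs gave most of the tRNA counts in both groups. Aspartate took 26.1% ± 7.25 of them in CT and 29.1% ± 15.0 in EU, alanine 15.0% ± 6.67 and 20.5% ± 16.2, lysine 13.8% ± 7.42 and 12.9% ± 5.84, and leucine 12.8% ± 3.02 and 10.2% ± 3.14 (SD, n = 5). The alanine share was 14.7% in CT and 9.87% in EU within A, C and D but 15.5% and 36.3% within G and H. Of 18 isotype shares, 0 passed the exact permutation test after adjustment, the smallest adjusted p being 0.400. The lowest unadjusted value was that of glycine, at 5.29% ± 0.83 and 3.88% ± 0.58 (exact permutation p = 0.0238, n = 5; 5.32% and 4.18% within A, C and D, 5.25% and 3.44% within G and H).

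Because EU replaces uridine, the uridine share of the captured sequences was compared. The count-weighted share was 21.9% ± 0.68 in CT and 19.7% ± 1.45 in EU (SD, n = 5; exact permutation p = 0.0317), lower in EU for all 5 letters, with 21.4% and 19.1% within A, C and D and 22.6% and 20.5% within G and H. The sign permutation within letters gave p = 0.0625. Without the 19-nt miR-238 sequence the difference was -1.16 percentage points (exact p = 0.119), and over tRNA sequences alone the means were 18.9% and 18.0% (exact p = 0.190). Across the 179 tested tRNA sequences, which are not independent, Spearman's rho between log2 fold change and uridine share was -0.233. Mean fragment length was 20.4 nt ± 0.60 in CT and 21.3 nt ± 1.54 in EU (exact p = 0.286, n = 5), with 20.9 and 22.3 nt within A, C and D and 19.8 nt in both groups within G and H.

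On the first principal component libraries parted by set of letters and not by group. This component, with 43.0% of the variance, ran from -12.0 in EU C to 15.7 in EU H, and the 4 libraries G and H lay above all 6 of A, C and D. The gap was narrow for letter G, with CT G at 3.22 and EU G at 1.27 against -0.60 in CT C. The H libraries lay much higher, with CT H at 12.7. The component did not part the groups (exact permutation p = 0.468). Spearman correlations between libraries ranged from -0.05 to 0.82. For G and H, the closest library to each was its letter partner of the other group, and for A, C and D it was a library of its own group and set of letters.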

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

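The tests of the Lys-CTT pattern, of a fixed miR-238 amount and of a batch, and the counts of splits except that for families, were chosen only after the results were seen, as was the margin of 2 SE on the slope over totals.

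In 108 groups of 5 values (2 groups for each of 54 reported quantities) 15 had a library far from the other 4, where chance, at about 1 in 20 groups, gives about 5.4. That number assumes independent and normally distributed values. The quantities overlap, and several have an SD above their mean, so the excess alone is no evidence of unusual libraries. In CT H the lysine share of tRNA counts was 26.8%, against 7.89 to 12.3% in the other CT libraries, with GCTCAGTCGGTAGAGC at 16088 CPM, ATAGCTCAGTCGGTAGAGC at 7050 CPM and the 25-nt Lys-CTT 5'-end sequence at 5423 CPM. In EU H, GCTCAGTCGGTAGAGC was at 5781 CPM, the 20-nt miR-238 sequence at 5605 CPM and the isoleucine share at 0.515%. EU D stood out for the Cys-GCA fragment GGGGGTATAGCTCAGTGGTAGAGC at 41679 CPM, for GCCCGGCTAGCTCAGTCGGTAGAGCATGG at 13373 CPM and for the proline fragment TGCGAGAGGTCCCGGGT at 1783 CPM. In CT C the cysteine share was 4.83% and the same Cys-GCA fragment was at 3319 CPM. In CT A the leucine share was 7.61%, the lowest of the group, and CGGGGTTCGATTCCCCGACGGGGAGCCA was at 111241 CPM. In EU A, ATCACGTCGGGGTCACCA of Trp-CCA was at 22088 CPM.

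The higher Lys-CTT 5'-end fragments in EU are the pattern closest to the study's question. Scaling between libraries was argued against by the within-library log2 ratio to Lys-TTT, which was higher by 2.50 in EU (exact p = 0.00794). Capture that follows the number of uridines alone was argued against by a Spearman rho of -0.0418 between fold change and uridine number, and by 2 pairs of Lys-CTT and Lys-TTT fragments of equal length and uridine number that differ by 1 base, which differed by at least 2.22 on the log2 scale. The pairs are the 25- and 26-nt forms of the same ends, so they amount to 1 comparison. The rho is weak support, as edgeR called none of the sequences behind it. A single EU library was not the whole of the Lys-CTT pattern, since the summed log2 fold change stayed at 1.98 or more without any one of them (unadjusted edgeR p at most 0.00154). Transfer of tagged fragments from T cells and a response of the β-cells whose RNA is carried over untagged both stay open, as untested here. They are not the only sources that the design leaves open. Chance was not excluded either: 28 of 100 splits of the libraries, the real one included and the others drawn at random, gave as many DESeq2 calls as the real 6 (highest other 55), and 14 of 100 gave 1 or more families as the real split did (highest other 6). In 46 of these splits the libraries of A, C and D lay evenly on both sides, as in the real one. Of these 46, the real one included, 6 reached its DESeq2 count and 3 its family count, so chance was still not excluded. Some of these splits repeat part of the real contrast. The split that exchanged only CT G and EU G gave 7 DESeq2 calls, and the one that exchanged only CT H and EU G gave 8. Both kept EU A, EU D and EU H together. Another, with CT A, CT G, EU A, EU C and EU G on one side, parted them and gave 10. The splits are thus not free of the real difference, and their counts cannot decide on chance.

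The lower miR-238 share in EU is the largest difference in the make-up of the libraries. A few abundant tRNA sequences were argued against as its source, since without the 5 most counted ones the log2 ratio of tRNA to miR-238 counts was still higher by 1.32 in EU (exact p = 0.0317). The total was argued against too, as its slope within groups accounts for 7.21% of the difference (35.2% at the slope minus 2 SE). A miR-238 RNA added in a fixed amount, with more tRNA-derived RNA in EU, may be the source. It would raise all 3 tRNA classes, and the smallest of their log2 ratios to miR-238 was 0.52, with exact p = 0.294, so this cannot be told apart from other sources with 5 libraries per group.

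On the first component the libraries of letters A, C and D lay apart from those of G and H. The exact permutation p was 0.00476, the smallest the 6 against 4 libraries allow, and both groups showed it, as a sequencing or library batch would. Letter H weighed most: CT G (3.22) and EU G (1.27) lay nearer to CT C (-0.60) than to CT H (12.7) and EU H (15.7). This component alone therefore does not show that G and H form a batch together. A difference in totals was argued against, the log2 totals differing by -0.0873 (exact p = 0.890). Splits of the libraries follow the same structure. The split that put CT A, CT C, EU A, EU C and EU D on one side, all 5 from the first set of letters, gave 16 edgeR calls where the real split gave 0, a count that each of the 100 splits reaches by construction and that says nothing of chance, and a split of the same kind gave 55 DESeq2 calls. The highest count of families, 6, came from splits with all 4 libraries of G and H on one side. With the letter as a block DESeq2 called 3 sequences and the Lys-CTT family kept an adjusted p of 0.0173. No biological explanation was tested for it.

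For the counts themselves chance was not excluded: 48 of 100 splits gave as many sequences at an unadjusted p below 0.05 as the real 11 (highest other 63), and 46 of 100 as many sets as the real 4 (highest other 7). Among the 14 drawn splits that part all 5 letters, as the real one does, DESeq2 counts reached 7 in another split, edgeR counts were 0 throughout, and the real split was 1 of 2 with 6 or more DESeq2 calls, 1 of 2 with 11 or more unadjusted ones, 1 of 3 with 4 or more sets and 1 of 2 with a family. The split with 7 DESeq2 calls differed from the real one only by the exchange of CT G and EU G, so it repeats most of the real contrast.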

How the results depend on the processing

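Results for letter sets, batch terms, permutation within batch, scaling to miR-238 or by the authors' factors, fits without miR-238, tRNA sequences only, summed families, ratios and all DESeq2 refits came from alternatives chosen after seeing the data. The count of 0 changed sequences with edgeR became 1 with library totals only, 6 with DESeq2, 7 with scaling to miR-238 counts and 1 when counts were summed by tRNA and position. Leaving out a library gave 0 to 4, with 4 without EU C and 1 without EU D, all higher Lys-CTT 5'-end sequences. The other alternatives gave 0. The DESeq2 count of 6 became 3 with the letter as a replicate block and 0 within G and H, stayed at 6 within A, C and D with 2 of them shared, was 5 with a batch term (the sixth, GCCCGGCTAGCTCAGTCGGTAGAGCATGA, got no adjusted p) and 5 without miR-238 (GCCCGGCTAGCTCAGTCGGTAGAGC at adjusted p = 0.0509), and ranged from 3 (without CT G or EU A) to 24 (without EU H, 18 of them lower in EU and 2 shared with the 6, of which 2 others got no adjusted p). The 4 set calls became 0 with an estimated correlation and 2 within G and H, and were 3 to 4 without single libraries. With fry, which tests a set against no change and so asks another question, 0 sets passed. The replicate block left edgeR at 0 and sets at 4. The uridine difference of -2.24 percentage points lost its call under the replicate block (same value), within A, C and D (-2.33) and within G and H (-2.10), where p below 0.05 cannot be reached by construction, and without the most counted sequence (-1.16) or over tRNA sequences only (-0.90). Leaving out a library gave -2.77 to -1.77. Of 4 class shares, 0 to 1 passed without single libraries, miR-238 without EU H. For values per library the replicate block cannot give p below 0.0625, so by construction it also ended the calls of both ratios (log2 differences of 2.50 and 1.56) and of the Lys-TTT 5'-end share. The replicate block changed no call of edgeR, sets or families. An exact permutation test within the sets of letters has 120 assignments and can reach the threshold. For the uridine difference and for both ratios this exact permutation test gave p = 0.0167. For the Lys-TTT 5'-end share the same exact permutation test gave p = 0.0333. The Lys-CTT 5'-end share (exact permutation p = 0.100) and the uridine share of tRNA sequences only (exact permutation p = 0.167) did not pass it. Other settings for the share of mitochondrial tRNA were not run, as no name marks one. Fragment length turned to -0.0045 nt within G and H. Totals, detection and isotype shares kept their side of the threshold under every alternative run. Apart from tests that cannot reach the threshold, the cause was not tested.

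Of 601 refits of single named sequences, 577 kept direction and side of the threshold, 19 moved past it and 5 turned: GGGGATGTAGCTCAGA of Ala-CGC to -0.45 within A, C and D, GCCCGGCTAGCTCAGTCGGTAGAGCATGG to -1.28 within G and H, and, scaled to miR-238 counts, GGGGATGTAGCTCAGT to 0.41, TGCGAGAGGTCCCGGGT to 0.19 and the 20-nt miR-238 sequence to 0.11, which that scaling holds near 0 by construction. It moved the median log2 fold change of all sequences from 0.05 to 1.26, with 94.0% of them higher against 54.9%, and upper-quartile factors moved it to -0.20 with 37.0% higher, so directions of small changes depend on the scaling. Many sequences had few counts per library and are imprecise. Among the 39 with a mean of 50 counts or more edgeR also called 0 (smallest adjusted p = 0.0580, 5 at an unadjusted p below 0.05), so it was not shown that low counts set the number of calls.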

Other observations

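The tests below were chosen only after the results were seen, apart from the ratio without the most counted sequences. The log2 ratio of 3'-CCA to internal counts was higher in EU for 4 of 5 letters (means of 1.01 ± 1.10 in CT and 2.07 ± 1.89 in EU, SD, n = 5; exact permutation p = 0.310), with means of 1.57 and 3.19 within A, C and D and 0.19 and 0.38 within G and H. The difference of 1.05 was 1.77 without EU H and 0.55 without EU C. Internal sequences took a smaller part of the tRNA counts in EU for 5 of 5 letters (19.3% ± 10.5 and 10.7% ± 9.01, exact p = 0.214; 14.1% and 5.38% within A, C and D, 26.96% and 18.6% within G and H). All 11 tested Asp-GTC 3'-CCA sequences had folds above 1, with a median of 1.63, and all 10 tested internal sequences shared by Lys-CTT and Lys-TTT had folds below 1, with a median of 0.659. The lysine median rested on the H libraries: it was 0.936 without CT H, where 3 of the 10 were above 1, and 0.378 without EU H. All 11 Asp-GTC sequences were above 1 without any one library, with medians from 1.27 to 2.05. With all libraries none of these 21 passed in edgeR, DESeq2 called none of them, and none had an unadjusted p below 0.05 in edgeR. Without EU H DESeq2 called 3 of the lysine ones, lower in EU, and scaled to miR-238 counts edgeR called ACCGGGGTTCGATTCCCCGACGGGGAGCCA of Asp-GTC, higher in EU. Overlapping pieces of 1 tRNA are not independent.

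In EU H the Lys-CTT 5'-end fragments were high (69082 CPM) although miR-238 held 39.6% of the counts, close to CT, whereas in EU C they were near background (10021 CPM) with miR-238 at 12.5% (95% Wilson interval 12.2 to 12.9%). The families Lys-CTT and Phe-GAA were high together in EU A, EU D and EU H and low together in EU C and EU G, with Phe-GAA 5'-ends at 11507, 8776 and 15471 CPM against 1160 and 934.

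The name miR-238 is that of a nematode miRNA, and such RNAs are commonly added to samples as controls. The labels do not say that one was added here. As a hypothesis, if it was added in equal amounts, the ratio of tRNA to miR-238 counts would follow the amount of tRNA-derived RNA captured. This ratio was 2.95-fold higher in EU (log2 means of 0.47 ± 0.54 and 2.03 ± 0.97, SD, n = 5; exact permutation p = 0.0238), higher in EU for 5 of 5 letters, with log2 means of 0.84 and 2.33 within A, C and D and -0.08 and 1.58 within G and H, and the sign permutation within letters gave 0.0625. Without the 5 most counted tRNA sequences the log2 difference was 1.32, and for internal sequences alone it was 0.52 (exact p = 0.294), so an even rise of all tRNA fragments was not shown.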
